A study of Homo sapiens with 2 samples.

How the data were processed

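Full-length human ETS1 W356C and the EGR1 DNA-binding domain were each measured on 1 array, per the labels. The labels' protocols state expression in E. coli, a GST tag and detection with a mouse antibody against GST that carries an Alexa 635 dye. The series' design text states 1 chamber of 1824 by 534 probes that together hold a de Bruijn sequence of order 12, with non-palindromic 10-mers in at least 35 probes. Scanner settings, background subtraction and normalization are not given in the sources used here.

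The deposited value of each probe is a score that the authors standardized to a mean of 0 and an SD of 1 over the listed probes, as its mean and SD show. The labels do not describe this step or any before it. The scores repeat at evenly related values, which allowed the scale before standardization to be worked out. The commonest score, equal to the median, was set to a quotient of 1, and the next commonest was tried at a simple fraction below it. The tied scores then fell on 1 straight line at simple fractions. Of 20000 checked probes per array, 100% for ETS1 and 99.97% for EGR1 lay within 1e-11 of a fraction with a denominator of at most 2500. Of random numbers 0% did. A quotient shifted or rescaled by a simple fraction would also pass, so this check does not fix where a quotient of 0 lies. The log2 values and folds rest on that choice. The scores were therefore read as a probe's intensity divided by a local reference and then standardized, and this quotient was recovered for each probe. That reading rests on the values, since neither the division nor the reference is stated per the labels. On this scale all quotients were above 0, and at most 81 ETS1 and 144 EGR1 probes can have been at the scanner ceiling of 65535. No subtraction of background is known, so folds over the median may be understated, most for the brightest words.

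The planned tests assumed an intensity column; they were run on log2 of the recovered quotient, whose median is 0 on each array. No normalization was applied between the arrays. Of 60 listed bases, the last 24 are the same in each probe, and words were counted in the 36 variable bases on both strands, with a word and its reverse complement as 1. Neighbouring probes in the listed order share 12 bases. The layout has 974016 spots, of which 41948 are not in the tables used here.

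The E-score of an 8-mer compared the brighter part of the probes holding it with the brighter part of all other probes by their ranks, on a scale from -0.5 to 0.5, and 0.45 was the threshold. Levels are medians of log2 signal minus the array median, with 95% percentile intervals from 2000 bootstrap draws over probes. Differences are between means of log2 signal, leaving out probes that hold both words, with two-sided permutation tests over probes (100000 permutations, 10000 for medians) and Benjamini-Hochberg adjustment within each family at 0.05. Spacings of paired cores were compared with the other spacings of the same orientation. Double substitutions were set against the sum of the single changes. Probes of 1 array are different sequences, so these intervals and p-values carry no replicate error, and the number of arrays limits the precision.

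Consensus words, word lists (8 ETS family, 8 zinc finger, 9 other and 4 composition words) and the planned tests and alternatives were fixed before the data were examined. Further tests and alternatives were added later, and the later parts state which were chosen after the data had been seen. The words named are the 10 8-mers of highest E-score per protein, the listed words, the 3 smallest and 3 largest losses by substitution, the consensus triplet and the 3 brightest others per finger, the 2 brightest and 2 dimmest flanked words, the brightest and dimmest spacing per orientation, and the 2 doubles farthest above and below the sum. Alternatives covered the E-score's form and threshold, a random part of the probes, GC content, further cores, position, strand, the choice of mean or median and the brightest probes. The scripts were tested on simulated values for the real probe sequences. Of 20 planted 8-mers among 32896 at each of 0.5, 1 and 2 log2, all 20 exceeded the limit set by unrelated words. Within their intervals lay 26 of 27 planted single changes and 310 of 324 additive doubles, and 4% of 400 null contrasts had a permutation p under 0.05. The simulated noise was independent between probes, without strand or position effects, and no planted double reached the background. These rates may therefore not hold for the real values. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, numba 0.67.0, scipy 1.17.1 and matplotlib 3.10.9 were used.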

Results

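Universal protein-binding microarrays were read for 2 human transcription factors. On such an array a tagged protein is added to very many DNA probes of known sequence and stained with a fluorescent antibody, so that the brightness of a probe reports how much protein stayed on that sequence. The proteins were full-length ETS1 carrying the substitution W356C and the DNA-binding domain of EGR1, both made in bacteria with a GST tag. ETS1 is the founding member of the ETS family, whose winged helix-turn-helix domain reads a GGA core, and EGR1 is an immediate-early factor that reads G-rich DNA through 3 zinc fingers. There was 1 array per protein and no array of unmutated ETS1 was analysed here. Each interval and p therefore covers the spread between probes of 1 array, not between experiments, and the 2 proteins were not compared as replicated groups.

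Both arrays listed the same 932068 probes, 95.7% of the spots of the stated layout. The probes are designed sequences without a place in the genome, with 36 variable bases followed by the same 24 bases. Each non-palindromic 10-mer lay in at least 35 probes, with a median of 48, and an 8-mer had a median of 824 probes. Signals are given as log2 of a probe's brightness relative to the local reference recovered from the deposited values, which puts the median probe of each array at 0. On the ETS1 array 4.77% of the probes exceeded 4-fold over the median, and on the EGR1 array 4.06% did.

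Which short words each protein bound was asked first. ETS1 W356C was brightest on words built around CCGGAA, led by CCGGAAGT with an E-score of 0.490 on a scale that ends at 0.5. Probes holding that word had a median log2 signal of 4.30 (95% interval 4.19 to 4.40, n = 834 probes), 19.7-fold over the array median. EGR1 was brightest on TGCGTGGG, a part of the G-rich site of its family, with an E-score of 0.490 and a median log2 signal of 3.20 (3.09 to 3.30, n = 834). The leading words of either protein lay near 0 on the other array, at -0.09 for CCGGAAGT and -0.02 for TGCGTGGG. Of 32896 8-mers, 56 exceeded an E-score of 0.45 on the ETS1 array and 78 on the EGR1 array. These counts depend on how the E-score is taken, with 11 and 23 when all probes enter it, 200 and 251 at a threshold of 0.40, and for ETS1 101 or 26 from word starts in the 5' or 3' part of the probe. No 8-mer exceeded 0.45 on both arrays, where 0.133 would be shared by independent lists, and the E-scores had a Spearman correlation of 0.119 across words, which are not independent replicates. Across the probes the correlation of the 2 arrays was 0.0755.

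All 56 ETS1 words held GGAA or GGAT. GGAA was in 41 of them and GGAT alone in 15, while CCGGA was in 30 and CAGGA in 4. The 10 highest E-scores belonged to CCGGAAGT, ACCGGAAG, CCGGAAAT, ACCGGAAA, CCGGATGT, ACCGGATG, CCGGAAAC, CGGAAGTG, CCGGAAGC and GCCGGAAG, down to 0.477. For EGR1, 50 of the 78 words held TGGG and another 19 held GGGG. Its 10 highest were TGCGTGGG, GCGTGGGC, CGTGGGCG, TGCGGGGG, GCGTGGGT, CGCGTGGG, GTGGGCGG, GCGGGGGC, GCGTGGGA and GTGGGCGT, down to an E-score of 0.483. The other 9 EGR1 words held neither, and, picked out after their values were seen, they comprised forms with GCGTGG such as GTGCGTGG (E-score 0.469) and forms with GTAGG such as CGTAGGCG (0.468).

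Textbook sites chosen beforehand were then measured on both arrays. The ETS consensus ACCGGAAGT reached a median log2 signal of 5.18 (4.97 to 5.28; SD 0.94, n = 200 probes) on the ETS1 array, 36.2-fold over the median, and -0.08 (-0.17 to -0.02) on the EGR1 array. The EGR1 consensus GCGTGGGCG reached 3.64 (3.53 to 3.77; SD 0.91, n = 213 probes) on the EGR1 array, 12.5-fold, and -0.04 (-0.10 to 0.04) on the ETS1 array. In the list of ETS family sites the 8-mers on the ETS1 array ran from 1.29 for TCGGAAGT to 4.30 for CCGGAAGT. Between them lay GAGGAAGT at 1.47, CAGGATGT at 1.96, CAGGAAGT at 2.87, CCGGAAAC at 3.39 and CCGGATGT at 3.58. The stromelysin-1 palindrome GGAAGCACTTCC was in 2 probes, at 1.22 and 3.96, too few for an interval. On the EGR1 array the members of that list lay between -0.09 and 0.05.

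The zinc finger list showed the reverse picture. On the EGR1 array GCGTGGGTG stood at 3.48, GCGGGGGCG at 3.37, GCGTGGGCA at 3.22, GCGTGGGAG at 3.08 and the shorter GTGGGCG at 2.60. Sites of related factors were dimmer there, with GGGGCGGGG, the GC box read by SP1, at 1.73 and GGGGTGTGG, a CACCC-type site read by KLF proteins, at 1.03, while GCGTGG alone gave 1.30. On the ETS1 array this list lay between -0.03 and 0.13. Among 9 sites of unrelated factors, which included CACGTGAC (E-box), ATGACTCA (AP-1), TGACGTCA (CRE), GGACTTTC (NF-kB type), AGATAAGA (GATA), TATAAAAG (TATA), TAATTAAC (homeodomain), TGTGGTTT (RUNX) and ATTTGCAT (octamer), levels ran from -0.03 to 0.03 for ETS1 and from -0.08 to 0.11 for EGR1. Of the composition words, GGGGGGGG reached 1.27 (1.20 to 1.33) and CGCGCGCG 0.66 (0.63 to 0.74) on the EGR1 array, against 0.16 and -0.01 on the ETS1 array. AAAAAAAA and TTTTAAAA were at -0.10 on the EGR1 array and -0.03 on the ETS1 array.

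**Figure D1:**
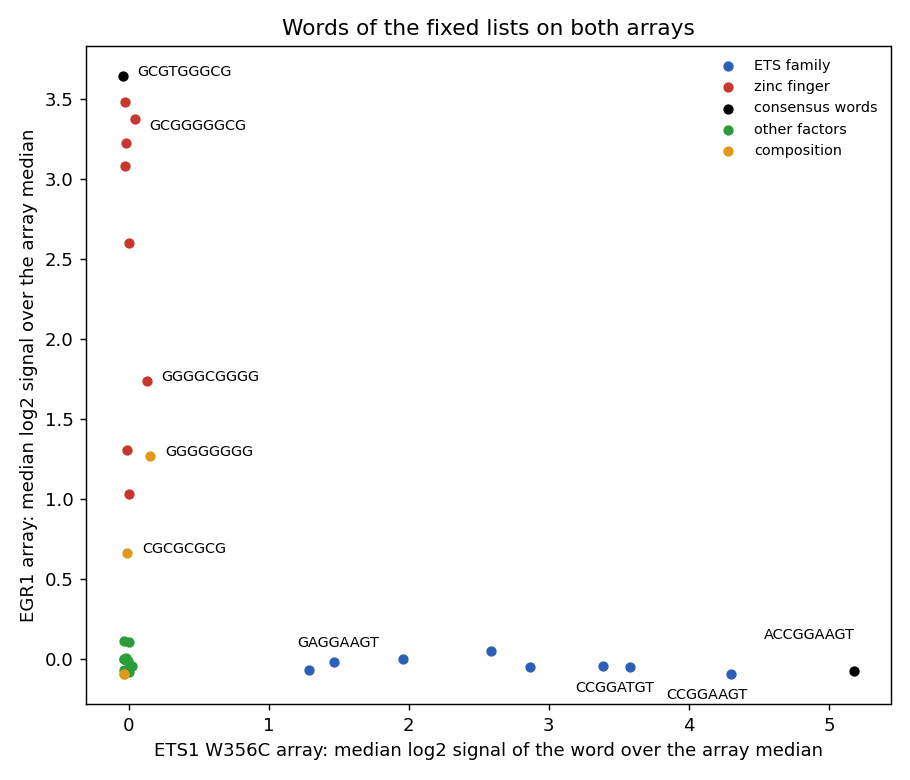
Median log2 signal over the array median of each word of the fixed lists and of the 2 consensus words, on the ETS1 W356C array (horizontal axis) and on the EGR1 array (vertical axis), 1 point per word. ETS family words spread along the horizontal axis up to the consensus ACCGGAAGT at 5.18. Zinc finger words spread along the vertical axis up to the consensus GCGTGGGCG at 3.64, and no word was bright on both.

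Single substitutions of the ETS consensus asked which bases carried the signal; positions are counted from 1 at the 5' end of ACCGGAAGT. All 27 substituted words were dimmer than the consensus on the ETS1 array. The GGA core tolerated least: G4C changed the mean log2 signal by -4.95 (-5.13 to -4.78, n = 194 probes against 200), G5T by -4.94 and G4A by -4.91, which left these words near the array median. The smallest losses were G8A at -0.38 (-0.57 to -0.19), A1G at -0.59 (-0.78 to -0.40) and A7T, which makes the GGAT core, at -0.64 (-0.84 to -0.45). In all, 16 substitutions lost more than 2 on the log2 scale and 4 lost less than 1. The largest adjusted permutation p (two-sided, Benjamini-Hochberg over 27 words) was 0.00015, for G8A; with the brightest 0.5% of probes left out, G8A fell by 0.18 with an adjusted p of 0.065. On the EGR1 array the same differences lay between -0.13 and 0.22.

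For EGR1, 26 of 27 substitutions of GCGTGGGCG were dimmer and 1 did not pass the test. The largest losses were at the last base of the first 2 triplets, where G3T changed the mean by -3.29 (-3.44 to -3.13, n = 206 against 213), G6A by -3.11 (-3.29 to -2.92) and G6T by -3.10 (-3.26 to -2.92). C8T gave -0.14 (-0.32 to 0.03; adjusted permutation p = 0.11), T4G -0.29 (-0.46 to -0.11; 0.0017) and G9A -0.34 (-0.53 to -0.16; 0.00024). Losses above 2 were seen for 10 substitutions, all at positions 3, 5, 6 and 7, and losses below 1 for 13. The mean change was -2.98 at position 3, -3.03 at position 6 and -2.44 at position 7, against -0.64 at position 1, -0.49 at position 8 and -0.61 at position 9. On the ETS1 array the same words differed from the consensus by -0.11 to 0.23.

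**Figure D2:**
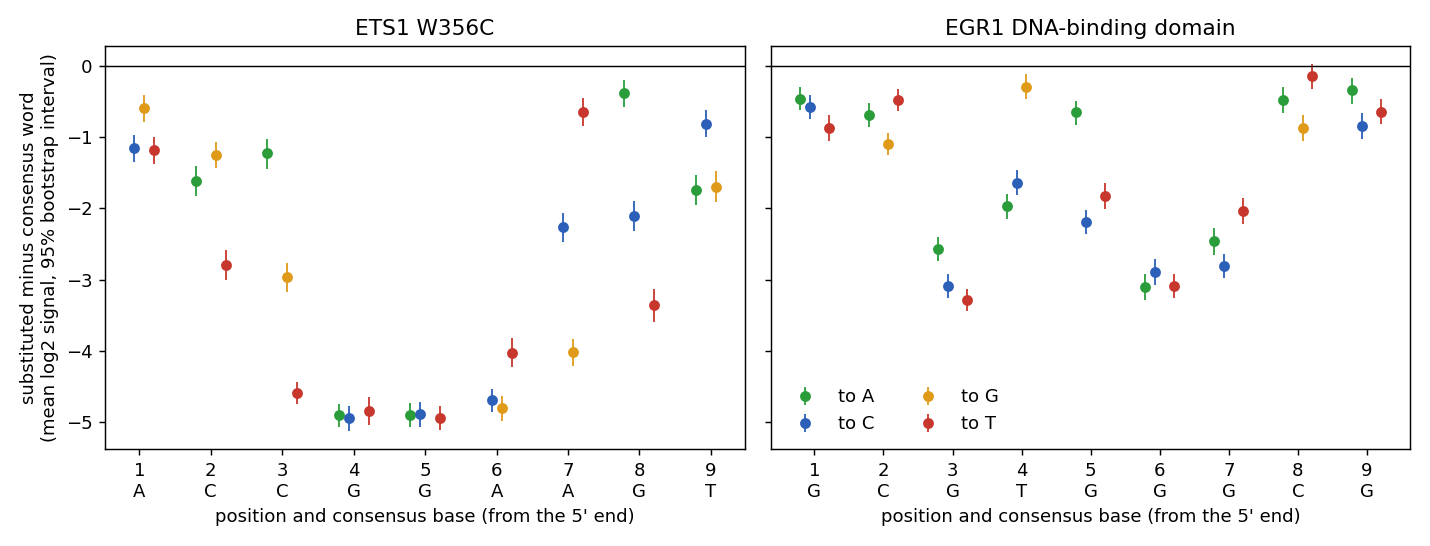
Mean log2 signal of each single-substitution word minus that of the consensus (vertical axis) by position in the site (horizontal axis), for ETS1 W356C (ACCGGAAGT) and EGR1 (GCGTGGGCG). Points are words coloured by the new base and bars are 95% bootstrap intervals over probes; the ETS1 losses reach -4.95 in the GGA core, and the EGR1 losses reach -3.29 at position 3.

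The 2 cores that ETS proteins accept were compared directly. ETS1 W356C was brighter on CCGGAAGT than on CCGGATGT by 0.67 on the log2 scale (0.55 to 0.79), or 1.59-fold, with means of 4.22 (SD 1.22, n = 830 probes) and 3.56 (SD 1.33, n = 823). The two-sided permutation p was 1e-05, the smallest that 100000 permutations can give. EGR1 was brighter on GCGTGGGCG than on GCGGGGGCG by 0.29 (0.11 to 0.47), or 1.22-fold (means 3.59 and 3.30, permutation p = 0.0017). Among sites on the opposite strand alone this EGR1 difference was 0.16 (-0.01 to 0.33; permutation p = 0.06).

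Each zinc finger of EGR1 contacts about 1 triplet of bases, so the 64 triplets were tried at each place with the other 2 kept. The consensus triplet ranked first at all 3 places. In the middle place TGG (mean log2 signal 3.59) was followed by GGG (3.30), TAG (2.94) and GAG (2.15), and only 3 triplets, TGG included, lay within 1 of the consensus. The first place took 8 triplets within that range, led after GCG by ACG (3.13), GTG (3.11) and CCG (3.01). With all probes the last place was the most permissive with 12, led after GCG by GTG (3.45), GCA (3.25) and GAG (3.12). With the brightest 0.5% of probes left out, 15 triplets of the first place came within 1 of the consensus. The ranking of the places by this count is therefore stated for all probes only. The median over all 64 triplets was 0.43 at the first place, 0.28 at the middle one and 1.27 at the last.

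Bases next to the sites were examined because the de Bruijn order of 12 covers words longer than the site. For ETS1 W356C the 16 words with 1 added base on either side spanned 0.95 on the log2 scale, from 5.60 for GACCGGAAGTC and 5.41 for AACCGGAAGTG to 4.76 for CACCGGAAGTA and 4.65 for CACCGGAAGTT. None of the 8 base contrasts passed the correction; the largest was a 5' G at 0.30 (0.01 to 0.58; permutation p = 0.054, adjusted 0.21). For EGR1 the words spanned 1.06, from 4.31 for TGCGTGGGCGG and 4.003 for TGCGTGGGCGT to 3.44 for CGCGTGGGCGT and 3.25 for GGCGTGGGCGA. Here too none of the 8 passed, and the largest was a 5' T at 0.32 (0.03 to 0.60; permutation p = 0.015, adjusted 0.12). Each word rested on 9 to 17 probes. The 5' T contrast passed under 4 alternatives and changed sign, to -0.05, with the brightest 0.5% of probes left out.

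Signal also depended on where in the probe a site lay and on its strand. Probes with 1 copy of CCGGAAGT on the listed strand had a mean log2 signal of 3.58 (SD 1.15, n = 404) on the ETS1 array, and those with the site on the opposite strand 4.83 (SD 0.93, n = 428), a difference of -1.26 (-1.40 to -1.11; permutation p = 1e-05, the smallest possible). For GCGTGGGCG on the EGR1 array the means were 3.02 (SD 0.80, n = 104) and 4.14 (SD 0.63, n = 109), a difference of -1.12 (-1.32 to -0.93; permutation p = 1e-05). ETS1 sites in the first 14 starts of the listed sequence were brighter than later ones by 0.80 (0.63 to 0.96), and the Spearman correlation of signal with start was -0.42 (-0.48 to -0.35) across 832 probes. For EGR1 the first 14 starts were brighter by 0.30 (0.04 to 0.55; permutation p = 0.017), with a correlation of -0.26 (-0.42 to -0.11) across 213 probes. Listed-strand words in the first 4 starts were dimmer than those in the next 4, by -1.09 (-1.25 to -0.95) for ETS1 and -1.15 (-1.28 to -1.02) for EGR1, over the consensus and its bright single substitutions. On the opposite strand the same difference was 0.07 (-0.05 to 0.19; permutation p = 0.23) for ETS1 and 0.11 (-0.0035 to 0.23; 0.059) for EGR1, and neither passed. For ETS1 that value averages unlike starts, since opposite-strand words relative to their own mean stood at 0.56 (SEM 0.065) at the first start and at 1.67, 1.88 and 1.84 at the next 3, a contrast not tested.

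**Figure D3:**
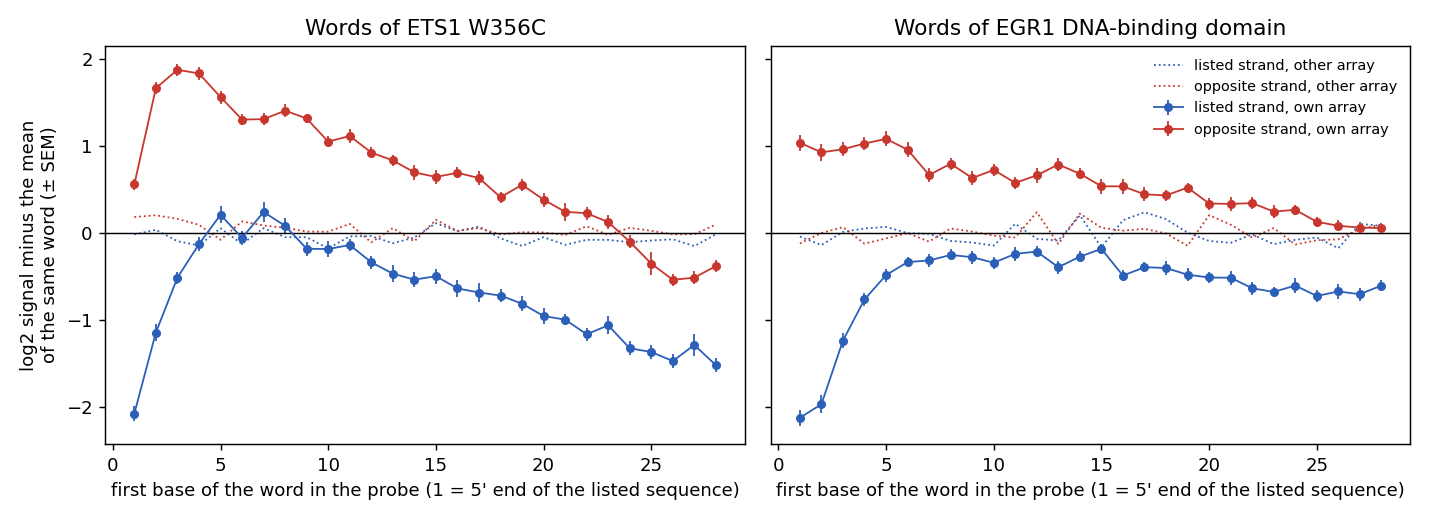
Log2 signal minus the mean of the same word (vertical axis) by the first base of the word in the probe (horizontal axis), averaged over 17 words for ETS1 W356C and 19 for EGR1, with bars of ± SEM over probes and dotted lines for the same probes on the other array. Words on the opposite strand lie above those on the listed strand on the protein's own array, and the dotted lines stay near 0.

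Full-length ETS1 is known to bind paired sites, and the arrangement of cores was tested for that reason. Mean log2 signal on the ETS1 array was 0.08 in 715454 probes without GGAA on either strand, 0.45 (SD 1.13) in 194339 probes with 1 core, 0.82 (SD 1.34) in 21112 with 2 and 1.17 (SD 1.43) in 1163 with 3 or more; on the EGR1 array these means lay between 0.14 and 0.17. The planned contrast, GGAA and TTCC 4 bases apart as in the stromelysin-1 promoter, was brighter than other spacings of that orientation by 0.11 (-0.03 to 0.25, n = 321 probes), which did not pass (permutation p = 0.11).

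Neighbouring cores differed more. TTCC directly followed by GGAA, which spells CCGGAA on both strands, exceeded other spacings by 1.46 (1.29 to 1.62, n = 339; adjusted permutation p = 0.00014), and TTCC and GGAA 1 base apart exceeded them by 0.27 (0.12 to 0.43; 0.0057). The dimmest spacing of that orientation, 26 bases, gave -0.58 (-0.98 to -0.07) in 30 probes and did not pass (adjusted permutation p = 0.16). A gap of 2 bases, named after its value was seen, was the spacing of this orientation that passed as dimmer, at -0.43 (-0.56 to -0.29, n = 322; adjusted permutation p = 0.00014). In the order GGAA to TTCC the brightest spacing was 1 base, at 0.59 (0.43 to 0.77), and the dimmest 0 bases, at -0.47 (-0.56 to -0.38), each with an adjusted permutation p of 0.00014. For GGAA repeated on 1 strand, a gap of 2 bases was brightest at 0.37 (0.25 to 0.48; 0.00029) and a gap of 24 bases dimmest at -0.42 (-0.62 to -0.18; adjusted permutation p = 0.031). Gaps of 24 and 26 bases leave room for the cores only near the ends of the variable bases. Listed-strand ETS1 words, relative to their own mean, stood at -2.07 at start 1 and -1.51 at start 28. Opposite-strand words stood at 0.56 and -0.38 there. Whether the wide gap or the place in the probe lowered the signal was not tested. On the EGR1 array TTCC and GGAA 1 base apart gave -0.19 (adjusted permutation p = 0.0012), opposite in sign to the ETS1 array, and the other arrangements named here gave -0.12 to 0.07.

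**Figure D4:**
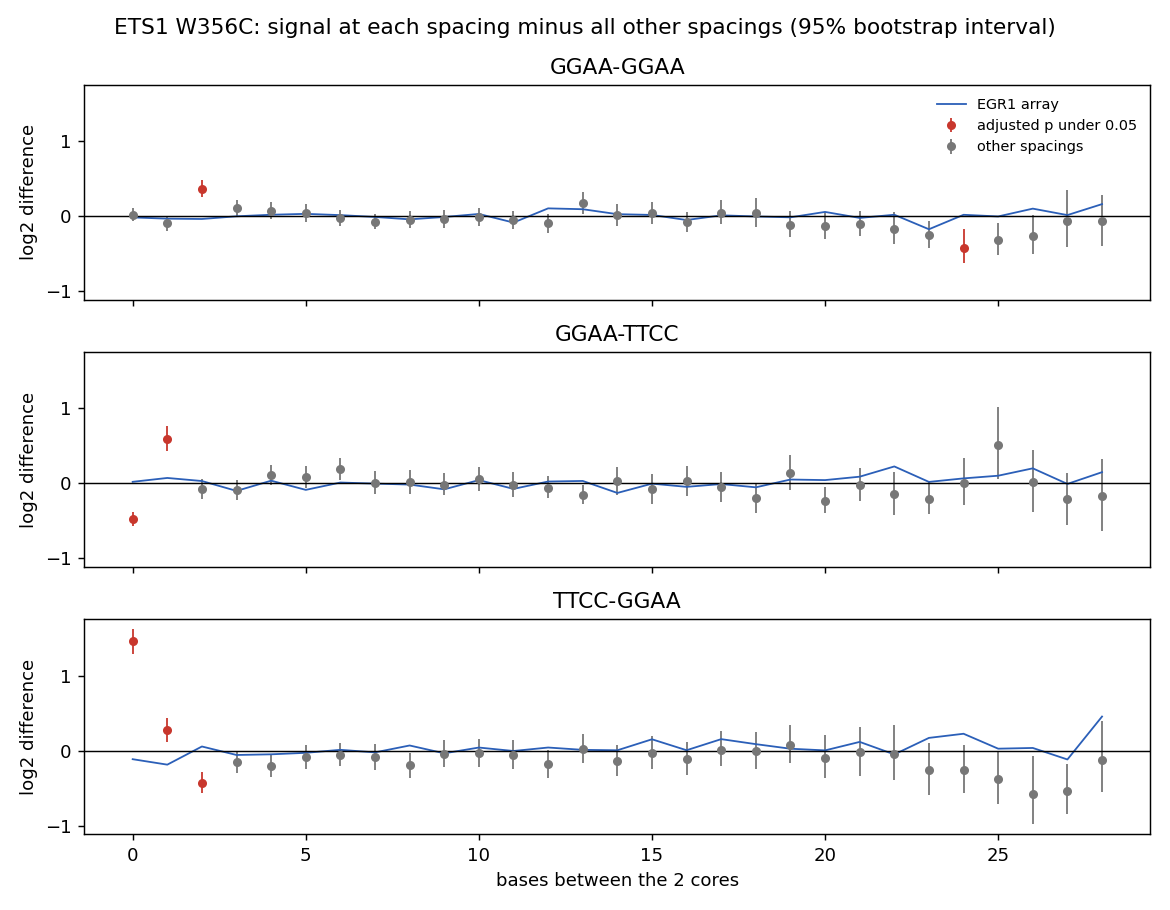
Mean log2 signal of probes with exactly 2 GGAA cores at each spacing minus that of all other spacings (vertical axis) by the bases between the cores (horizontal axis), 1 panel per relative orientation, with 95% bootstrap intervals; the line gives the same probes on the EGR1 array. The spacings that passed lie at 0 to 2 bases and at 24, and the highest is 1.46 for TTCC directly followed by GGAA. Spacing was not separated from the bases that 1 core fixes beside the other at 0 to 2 bases. Nor was it separated from the place of the cores in the probe at 24.

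Pairs of substitutions showed how far positions acted independently. Over all double substitutions of the ETS site the observed change and the sum of the 2 single changes had a Pearson correlation of 0.823 across words, which are not replicates. Many sums lie below the array background, where no further loss can be seen, and 231 doubles stayed above the sum by more than their interval, led by G4C with G5T (ACCCTAAGT, 5.07 above) and G4C with G5A (ACCCAAAGT, 4.99 above). Among the 105 doubles with a sum above background the correlation was 0.970, and 83 lay within their interval of the sum, 12 above and 10 below. A7T with G8C (ACCGGATCT) lay farthest below, at -0.56 (-0.84 to -0.26), followed by A1C with C2G (CGCGGAAGT) at -0.51 (-0.81 to -0.21).

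The doubles of the EGR1 site were set against the sum in the same way. Of 212 doubles with a sum above background, 86 lay within their interval of the sum, 45 above and 81 below, with a correlation of 0.909. Over all of its doubles 152 were above, or 98 with the brightest 0.5% of probes left out, and 81 below, and G3C with G6C (GCCTGCGCG, 3.08 above) and G3T with G6T (GCTTGTGCG, 2.99 above) stood farthest above, both with sums under the background. T4G with G5C (GCGGCGGCG) lay farthest below, at -0.81 (-1.06 to -0.57), and T4G with G5T (GCGGTGGCG) at -0.79 (-1.04 to -0.56), although T4G alone gave -0.29.

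The precision of word signals fell with word length. Between random parts of the probes, median log2 signals of 8-mers had a Pearson correlation of 0.972 for ETS1 and 0.978 for EGR1, 10-mers of 0.762 and 0.796, and 12-mers of 0.0893 and 0.135. Spearman correlations, in which the many unbound words weigh more, were 0.416 and 0.837 for 8-mers.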

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

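All tests in this part were chosen after the position and strand differences had been seen, except the tests on probes without a second core. The fall of signal along the probe differed between these 2 arrays, by a test over probes that cannot separate protein from array. Beyond the first 4 starts, log2 signal changed per base by -0.0760 (-0.0813 to -0.0709) for ETS1 W356C and -0.0190 (-0.0227 to -0.0151) for EGR1 among listed-strand words, a difference of -0.0570 (-0.0639 to -0.0506; permutation p = 0.0001, the smallest that 10000 permutations can give). On the opposite strand the slopes were -0.0878 and -0.0376, a difference of -0.0502 (-0.0563 to -0.0440; permutation p = 0.0001). The words were 17 for ETS1 and 19 for EGR1, each centred on its own mean. With 1 array per protein, whether the protein, its length (whole protein against a domain) or the array makes the difference was not tested. The EGR1 words were also dimmer, with a consensus mean of 3.59 against 5.03 for ETS1. Whether less signal over an unsubtracted background flattened the EGR1 slope was not tested either.

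The strand difference was weighed as well. All 17 ETS1 words and all 19 EGR1 words were dimmer on the listed strand, by a median of -1.37 and -1.10. Brightness of these probes without a bound site is argued against by the other array. There the same probes differed by -0.0665 (-0.169 to 0.0370) for the ETS1 site and -0.115 (-0.356 to 0.129) for the EGR1 site. Both sites lay near the median of that array, so a property of the probes that scales bound signal could not show and stays open. Uneven starts do not account for the strand difference, since within starts it was -1.29 (-1.40 to -1.16) and -1.08 (-1.31 to -0.89). Nor do further sites, since probes without a second core gave -1.32 (-1.49 to -1.16) and -1.15 (-1.36 to -0.97). Another candidate explanation that stays open, and was not tested, is that the orientation of the bound protein to the slide changes binding or staining of its tag.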

How the results depend on the processing

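The alternatives that used position-adjusted signals or the deposited scores in place of log2 were chosen after seeing the data. No paired analysis was possible because each protein had 1 array. The ETS1 core contrast, the ETS1 flanks, site strand and position, the planned paired-core spacing and the absence of 8-mers shared by both proteins kept their direction and side in each alternative run. The paired-core difference ranged from 0.06 to 0.17 on the log2 scale, with p from 0.077 to 0.47. Counts of 8-mers moved. With all probes in the E-score 11 ETS1 and 23 EGR1 words passed, and at a threshold of 0.40 there were 200 and 251. ETS1 had 101 words from starts in the 5' part of the probe and 26 from the 3' part. The level of ACCGGAAGT was 5.43 in the 5' and 4.64 in the 3' part, 4.53 on the listed and 5.55 on the opposite strand, and 4.39 without the brightest 0.5% of probes. GCGTGGGCG gave 3.97, 3.47, 3.23, 4.17 and 3.30 in that order. On the opposite strand the GCGTGGGCG to GCGGGGGCG difference, 0.16, no longer passed. The 5' T flank of EGR1 passed on the opposite strand (0.43), by medians (0.48), as a deposited score (1.38) and adjusted for position and strand (0.24, adjusted permutation p = 0.018), and turned to -0.046 without the brightest probes; adjusted permutation p ranged from 0.0043 to 0.96. Without those probes 98 EGR1 doubles lay above the sum and 15 first triplets came within 1 of the consensus. Leaving the brightest probes out lowers bright words by construction; the cause of the other changes was not tested. Of the single substitutions named, 117 values under alternatives kept their side, G8A and T4G lost theirs once each, and C8T passed once, when adjusted for position and strand (-0.23). Another intensity column, a spatial correction and a floor for values at or below 0 were not run, because the tables used here hold 1 value column, no spot positions and no such quotient. Signal over background limits the largest ETS1 losses, which end at the array median.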

Other observations

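The tests in this part on bright probes, on palindromic words and, taken separately, on strands and further sites for T4G were chosen after the values had been seen, and so were the signed comparison within and across triplets and the use of signals adjusted for position and strand. Bases up to 4 positions beyond either consensus, with signals adjusted for position and strand, gave 0 of 32 contrasts that passed for ETS1 and 0 of 32 for EGR1 (permutation tests, Benjamini-Hochberg), and small effects stay open at this number of probes. Limited to the 8 contrasts of the adjoining bases, the same adjusted signals gave 2 for EGR1, a 5' T at 0.24 (0.05 to 0.41) and a 3' G at 0.23 (0.08 to 0.37), each with an adjusted permutation p of 0.018. Palindromic 8-mers without a bound core did not differ detectably from other words in mean E-score, by 0.000757 (-0.0063 to 0.00797) for ETS1 and -0.00178 (-0.0134 to 0.0103) for EGR1.

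EGR1 double substitutions departed from the sum in different directions: among those with a sum above background, the 51 within a triplet lay 0.19 (SD 0.36) above it and the others, across triplets, -0.18 (SD 0.35) from it, a difference of 0.37 (0.26 to 0.48, permutation p = 1e-05 over words, the smallest possible). The words share the means of the 27 single substitutions and of the consensus. They are therefore not independent, and the intervals and p-values over words given here do not allow for that. The means also differed between triplets, at 0.18 within the first, -0.09 within the middle and 0.31 within the last. The planned hypothesis, a larger absolute departure within triplets, was not borne out (-0.000556, -0.0769 to 0.0714; permutation p = 0.99). Matching on the summed loss left 0.346 (0.25 to 0.46), which argues against the floor at the background, while doubles 1 or 2 positions apart gave 0.0937 (-0.07 to 0.26; permutation p = 0.3), so the distance between positions may account for the difference as well as the triplet. Within the middle triplet, at -0.09 (SD 0.47) over 10 doubles, T4G with G5C and with G5T deviated by -0.90 (-1.16 to -0.64) and -0.844 (-1.09 to -0.59) over probes without a second core, which argues against further sites, by -1.19 and -1.08 on the opposite strand, and by -0.474 (-0.76 to -0.19) and -0.56 (-0.84 to -0.27) on the listed strand, so that a part played by strand stays open. They lay -0.572 from the median of doubles of like summed loss, but were picked as the farthest below the sum, and T4G with G5A deviated by -0.51 (-0.77 to -0.24), which holds its peers' median of -0.28, so compression of bright words stays open beside a dependence between positions 4 and 5, and the position of the words in the probe was not tested.

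Of 348278 probes without any 8-mer above an E-score of 0.2 on either array, 7804 exceeded 4-fold on the ETS1 array and 4740 on the EGR1 array. Overlapping neighbours, which share 12 bases, exceeded 4-fold in 4.32% (exact binomial interval 4.01 to 4.66%) for ETS1 and 3.04% (2.70 to 3.40%) for EGR1. The shares were 4.02% and 3.20% around all such probes, and 13.2% and 16.9% around bright probes with a core. The E-score limit came from these same data, so it had already removed probes with a short site that brightens many probes. The shares cannot decide on such sites, and argue only against longer sites within the shared bases. Of the 348278 probes, 1093 were bright on both arrays where 106 would be by chance. That is 14.0% of those bright on the ETS1 array and 23.1% of those bright on the EGR1 array. A property of the probe or its spot that recurs on both arrays may therefore account for a part of the bright probes. How large a part stays open, since signal under 4-fold on the other array was not examined. The neighbours can show only sites that lie wholly within the shared bases. Other sites, short or long, and spots bright on 1 array by accident stay open and were not tested.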
